A study of Mus musculus with 55 samples.

How the data were processed

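RNA was measured by CEL-seq, which barcodes cDNA at the 3′ end of each transcript, from 10 ng of total RNA per the labels. The deposited tables hold the count of each gene in each library, mapped to mm10 per the labels and not normalised. 1 table holds 8 epiblast stem cell (EpiSC) libraries and 15807 genes, the other 9 embryo libraries and 14602 genes. The 8 spike-in entries of each were left out, and held 2 reads and 1 read over all libraries. By symbol, 99.53% and 99.57% of the genes were found in the GRCm38 gene table, from which chromosome positions were taken.

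Each table was fitted alone with edgeR's quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest), TMM scaling and 1 mean per group, after filterByExpr left 9703 genes in EpiSCs and 6003 in embryos. The residual degrees of freedom were 4 and 6, and the common biological coefficients of variation 0.081 and 0.0995. A gene was called when its Benjamini-Hochberg adjusted p over all tested genes was below 0.05. Adjusted p-values of single genes below come from this test unless another is named, standard errors of log2 differences from its F statistic, and CPM, the counts scaled to a common library size, from TMM-scaled totals. The interaction is the 24h response of Null cells minus that of WT cells. Where a group held 0 counts of a gene, a fold is given as a lower bound from a floor of 3 counts over the group; where it held 1 to 3, the ratio of pooled counts carries an exact interval. These intervals and floors cover counting error only. The labels do not say whether replicates came from separate cultures or animals.

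Before the data were examined, 25 gene lists and the rule for named genes were fixed. Lists with at least 3 tested members were compared with all other genes by camera from limma, apart from the exceptions below. The preset correlation between genes was 0.01, and p-values were adjusted by Benjamini-Hochberg within each comparison. The Cdx list, with 3 tested members in embryos, was left out of the list tests there. The sex-linked list, with 4 tested members in EpiSCs, was left out where Null was compared with WT and in the interaction. Each list tested by camera was also tested with an estimated correlation and with fry. The lists covered Cdx genes, sex-linked genes, Hox paralog groups 1 to 4, 5 to 9 and 10 to 13, primitive streak and axial progenitor genes, Wnt feedback and target genes, Wnt ligands, R-spondins and receptors, Fgf ligands, receptors and feedback genes, presomitic and paraxial mesoderm genes, Bmp and Nodal pathway genes, retinoic acid pathway genes, epiblast and pluripotency genes, neural, notochord, endoderm, allantois and extraembryonic mesoderm, blood and endothelial, and cardiac and lateral plate mesoderm genes. The others held cell cycle, p53 target, hypoxia and glycolysis, immediate early and heat shock, mitochondrial and fibroblast genes. Hox groups 10 to 13 and mitochondrial genes had too few tested members in both tables. Named genes are Cdx1, Cdx2, Cdx4 and T, the 6 called genes with the largest rise and the 6 with the largest fall in each comparison at a mean of at least 20 CPM in the higher group, and up to 3 members of selected lists with the smallest p. Predicted genes were not named, and outside the interaction the libraries of both groups had to be fully separated.

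Data with known differences were simulated 1 time per comparison at the depth of these tables. Every gene was given the mean spread over genes, so differences in spread between genes are not covered. Per comparison, 90 to 100 tested genes were given a log2 difference of 1 in size, and 93 to 100 one of 2. The Benjamini-Hochberg adjustment depends on how many genes change, so the shares below hold for that number. Many more genes were called in the real 24h responses. Of genes with a true log2 difference of 1, 71.1% were called for WT at 24h against 0h and 58.8% for Null. The share was 58% for Null against WT at 0h, 62.2% at 24h and 29.3% for the interaction. In the embryo design it was 64.4% for Triple against WT, 73.2% for Cdx1-4 against WT and 75% for Triple against Cdx1-4. For a true difference of 2 these shares lay between 76.8% and 99%, and between 1.97% and 6.67% of the calls were false.

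Binding, acetylation and accessibility came as deposited lists of regions in mm9, 1 per sample, which hold positions without a score. Per the labels, ChIP reads were aligned with Bowtie 1.1.0 and handled with SAMtools 0.1.19, ATAC-seq reads were trimmed with cutadapt 1.8.1 and aligned with Bowtie2 2.1.0, and peaks were called with MACS2 2.1.0. Sites of Cdx2 and of T are regions of either replicate that overlap a region of the other by at least 1 bp, merged where they overlap or touch. Overlap shares carry 95% Wilson intervals and stand beside the mean over 100 shuffles of the same sites within their chromosomes. The same sites were compared between E9.5 tissues with an exact two-sided McNemar test, between ATAC-seq times as values without a test, and regions with each other by Fisher's exact test, two-sided. Regions of the 8 input samples, 1263 after merging, were not removed from the lists, except in an alternative run. RNA positions are in GRCm38 and binding sites in mm9, and the builds are not mixed. The 17 4C samples were not analysed here.

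The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 for an alternative fit, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.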

Results

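The series holds 55 mouse samples, which measure gene expression, protein binding, chromatin marks and accessibility around the Cdx and T transcription factors of the axial progenitors that build the trunk and tail. RNA came from EpiSCs, pluripotent lines made from pre-streak embryos and grown with Fgf-basic, Activin A and the Wnt inhibitor IWP2. WT and Null EpiSCs were sampled at 0h and after 24h with the GSK3 inhibitor Chiron, which activates Wnt signalling, and Fgf8, with 2 libraries in each of the 4 groups. RNA also came from tailbuds dissected at E8.0, with 3 libraries each of WT, Cdx1-4 and Triple embryos. The labels do not spell out the genotypes behind Null, Cdx1-4 and Triple, and the culture text given for the Null EpiSCs mentions cells null for Wnt3. EpiSC libraries held 1114055 to 2914870 counts and embryo libraries 389601 to 854852, so that a floor of 3 counts in 1 library is 1.03 to 2.69 CPM in EpiSCs and 3.51 to 7.7 CPM in embryos. The 10 most abundant genes took 7.77% to 9.75% of the counts of a library. ChIP-seq lists covered Cdx2, T and H3K27ac in EpiSCs at 24h with 2 replicates each, and CBP-P300 with 1. H3K27ac, a mark of active enhancers and promoters, was also mapped at E9.5 in anterior tissue and tailbud with 2 replicates each. ATAC-seq mapped open chromatin in CdxKO EpiSCs at 0h and at 48h with Chiron alone, with 1 library each.

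The Cdx genes, homeobox regulators of posterior identity, were measured first in every library to see how the group names read out at the level of RNA. In EpiSCs their transcripts were scarce, and Cdx1 and Cdx4 were too low to test. Cdx2 (GRCm38 5:147300900-147307249) rose in WT cells from 3.03 ± 0.26 to 21.8 ± 11.9 CPM (SD, n = 2), a log2 difference of 2.91 ± 0.52 (SE, edgeR adjusted p = 2.3e-04), with 6 and 5 counts at 0h and 87 and 21 at 24h. Null cells also held Cdx2 transcripts, with 0 and 6 counts at 0h and 21 and 19 at 24h, and their rise of 2.31 ± 0.71 was called (edgeR adjusted p = 0.0237). That call was lost without Null 0h replicate 1 (adjusted p = 0.34, the highest over its alternatives), Null 24h replicate 1 (0.0701) or Null 24h replicate 2 (0.0942), with DESeq2 (0.0769) and after thinning to equal library totals (0.0524). Cdx2 was the only Cdx gene tested in EpiSCs, so an adjustment over the list alone would correct for nothing and is not given. At 24h Cdx2 differed between Null and WT by -1.02 ± 0.40, which did not pass over all genes (edgeR adjusted p = 0.126). It did pass without WT 24h replicate 2 (adjusted p = 0.01), without the filter (0.025) and with only the libraries of the compared groups (0.0389). At 0h the difference was -0.42 ± 0.92 (adjusted p = 0.852), and in the interaction -0.60 ± 1.07 (0.908). Cdx1 (18:61018862-61036199) held 2 and 1 counts in WT at 0h, 16 and 7 at 24h, 2 and 2 in Null at 0h and 9 and 7 at 24h. Cdx4 (X:103321398-103330224) held 2 counts in WT 0h replicate 2 and 0 in the other EpiSC libraries. The counts come from 3′ ends, so transcripts that lack another part of the gene are counted too.

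In tailbuds the embryo groups differed in all 3 Cdx genes. Cdx4 held 68 counts in WT, 1 in Cdx1-4 and 0 in Triple, which makes it at least 19.2-fold lower in Triple and gives a WT to Cdx1-4 ratio of 82.3 (exact interval 14.3 to 3297). Cdx1 fell from 182 ± 32.6 CPM in WT to 61.7 ± 18.5 in Cdx1-4 and 75.8 ± 31.8 in Triple (SD, n = 3), log2 differences of -1.60 ± 0.21 (edgeR adjusted p = 5.1e-06) and -1.27 ± 0.22 (1.3e-04). Cdx2 fell in Triple embryos to 100 ± 15.3 CPM from 212 ± 49.8 in WT (log2 difference -1.12 ± 0.19, edgeR adjusted p = 1.5e-04). Cdx1-4 embryos held 206 ± 54.2 CPM of Cdx2, a difference from WT of -0.12 ± 0.17 (edgeR adjusted p = 0.918). T (17:8434423-8442496), the T-box factor of the streak and tailbud, was 108 ± 8.80 CPM in Triple, 186 ± 16 in Cdx1-4 and 194 ± 26 in WT. Its difference was -0.85 ± 0.17 between Triple and WT (edgeR adjusted p = 9.0e-04) and -0.09 ± 0.15 between Cdx1-4 and WT (0.937). Among the libraries whose columns are named blue, Cdx2 and T differed between Triple and WT by -0.79 and -0.72, with an adjusted p of 0.121 for both.

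**Figure D1:**
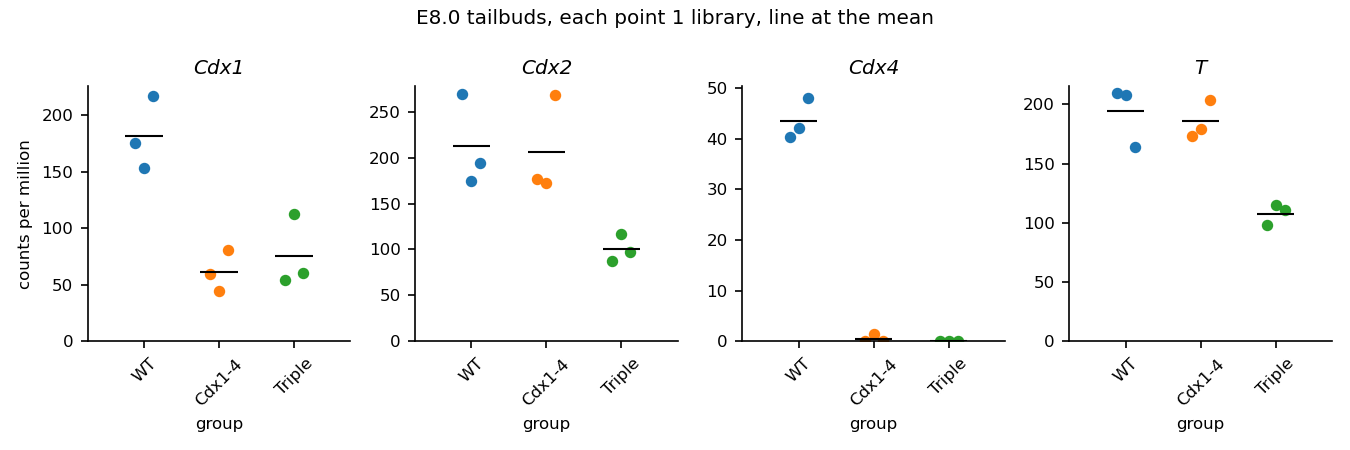
CPM of Cdx1, Cdx2, Cdx4 and T in each E8.0 tailbud library (points, n = 3 per group) with group means (lines). Cdx4 is at or near 0 in the Cdx1-4 and Triple libraries, while Cdx2 and T are lower in Triple libraries than in both other groups.

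Triple tailbuds held fewer posterior Hox transcripts than WT. Hoxb9 fell from 213 ± 56.2 to 5.77 ± 5.52 CPM (SD, n = 3), a log2 difference of -4.92 ± 0.36 (edgeR adjusted p = 3.6e-12). Hoxb8 and Hoxd9 changed by -3.24 ± 0.28 and -2.54 ± 0.41. Of the 8 measured Hox genes of paralog groups 5 to 9, which pattern the trunk, 6 fell (7 adjusted over the list alone; camera adjusted p = 1.3e-22). The list passed with an estimated correlation too (adjusted p = 0.0109 with an estimated correlation). Among the more anterior groups 1 to 4, Hoxd4 fell by 2.81 ± 0.55 (edgeR adjusted p = 0.00545, and 0.0556 without Triple replicate green-1, the highest over its alternatives). Of these 10 genes 1 rose and 1 fell, with 1 and 3 adjusted over the list alone (camera Down, adjusted p = 0.0487, and adjusted p = 0.18 with an estimated correlation).

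Genes of the streak and axial progenitors fell with them. Grsf1, an RNA-binding protein gene, fell from 324 ± 43.7 to 122 ± 8.78 CPM (log2 difference -1.42 ± 0.16, edgeR adjusted p = 7.2e-09), Evx1, a homeobox gene of the posterior streak, changed by -1.29 ± 0.21 and the ligand gene Wnt5b by -2.17 ± 0.39. In this list 5 of 10 measured members fell, with 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 3.0e-11, and adjusted p = 0.00643 with an estimated correlation). The presomitic and paraxial mesoderm list split. Tbx6, needed to make presomitic mesoderm, and Cited1 changed by -1.68 ± 0.21 and -0.93 ± 0.12, whereas Meox1, a gene of formed somites, rose from 38.6 ± 7.77 to 222 ± 28.4 CPM (log2 difference 2.56 ± 0.21, edgeR adjusted p = 7.0e-13). Of its 15 members 4 rose and 5 fell (7 and 7 adjusted over the list alone), and the list test did not pass (camera Down, adjusted p = 0.803; median -0.58, mean 0.09). Epiblast genes leaned down, with 2 of 10 lower (3 adjusted over the list alone; camera adjusted p = 0.0293, and adjusted p = 0.18 with an estimated correlation).

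Sox10, Col2a1 and genes of retinoic acid handling rose in Triple tailbuds. Sox10, a regulator of neural crest, rose from 2.47 ± 2.44 to 108 ± 7.0 CPM (log2 difference 5.03 ± 0.39, edgeR adjusted p = 2.5e-13), and Col2a1, a collagen of notochord and cartilage precursors, rose by 3.79 ± 0.46. The retinoic acid pathway list rose with 4 of 9 members up and 1 down, the same counts as adjusted over the list alone (camera adjusted p = 0.0132, and adjusted p = 0.28 with an estimated correlation). It did not pass with fry either (fry adjusted p = 0.112). Aldh1a2, the enzyme that makes retinoic acid in the trunk, rose from 305 ± 13.5 to 781 ± 150 CPM, the binding protein gene Crabp2 by 1.26 ± 0.17 and the vitamin A uptake receptor gene Stra6 by 1.16 ± 0.18. The endoderm list rose as well, with 5 of 21 members up and 1 down, also adjusted over the list alone (camera adjusted p = 9.8e-05, and adjusted p = 0.18 with an estimated correlation). This list also did not pass with fry (fry adjusted p = 0.108). Its keratin genes Krt18 and Krt8 rose by 0.76 ± 0.13 and 0.66 ± 0.13, and the endocytic adaptor gene Dab2 by 0.77 ± 0.16. Prl8a2, a prolactin family gene of the decidua, held 35 counts in Triple and 1 in WT, a ratio of 41.4 (exact interval 6.96 to 1681).

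Wnt and Fgf genes moved in both directions. The Wnt antagonist Sfrp1 rose from 111 ± 4.9 to 250 ± 39.7 CPM and the receptor gene Fzd2 by 0.96 ± 0.15, against the fall of Wnt5b. Among Wnt ligands, R-spondins and receptors 1 of 9 rose and 2 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.0567), and among Wnt feedback and target genes 2 of 10 rose and 1 fell (2 and 3; 0.803). Fgfr2 rose from 18.2 ± 6.25 to 77.4 ± 20.3 CPM, while Il17rd, an Fgf feedback inhibitor, fell by 1.27 ± 0.28 (edgeR adjusted p = 0.00305, and 0.0502 among the blue libraries, the highest over its alternatives). Of 12 Fgf genes 1 rose and 4 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.16). In all, edgeR called 174 genes, 97 higher and 77 lower in Triple. The Bmp and Nodal, allantois, immediate early, notochord, neural, fibroblast, p53 target, hypoxia and cell cycle lists did not pass (camera adjusted p from 0.0667 to 0.803). Median and mean differed in sign for allantois genes (0.39 and -0.13, tested upward) and fibroblast genes (0.33 and -0.28, tested downward). DESeq2 called 91 genes, and the libraries with blue column names alone, 2 per group, called 74.

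Cdx1-4 tailbuds differed from WT in few genes. Beyond Cdx1 and Cdx4, edgeR called 6 genes, for a total of 2 higher and 6 lower. Tecr, an enzyme of fatty acid elongation, fell by 0.68 ± 0.12 (SE, n = 3; edgeR adjusted p = 8.3e-04), the Wnt antagonist Frzb changed by -1.25 ± 0.21, and Meg3, an imprinted non-coding RNA, rose by 0.76 ± 0.14. Without WT replicate green-1 these 3 were no longer called (adjusted p = 0.093, 0.121 and 0.0597), and over the alternatives their adjusted p reached 0.336, 0.158 and 0.351. Hoxb9 and Hoxb8 differed by -0.41 ± 0.19 and -0.25 ± 0.18 (edgeR adjusted p = 0.627 and 0.819), and Sfrp1 by 0.21 ± 0.18 (0.839). Camera passed 0 of 19 lists, 1 at an unadjusted p under 0.05, and fry 0; the lowest adjusted p was 0.335 for hypoxia and glycolysis. DESeq2 called 4 genes.

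Triple tailbuds were also compared with Cdx1-4 tailbuds, groups that share low Cdx1 and Cdx4 and differ in Cdx2 by -1.01 ± 0.19 (edgeR adjusted p = 9.8e-04). Hoxb9 was lower in Triple, at 5.77 ± 5.52 against 156 ± 36.7 CPM, a difference of -4.52 ± 0.37, and Hoxb8 and Hoxd9 differed by -2.99 ± 0.28 and -2.31 ± 0.41. Hox groups 5 to 9 fell with 6 of 8 members (7 adjusted over the list alone; camera adjusted p = 3.2e-22, and adjusted p = 0.0114 with an estimated correlation). The streak list fell with 4 of 10 members (7 adjusted over the list alone; camera adjusted p = 6.6e-11, and adjusted p = 0.00704 with an estimated correlation), Grsf1 by -1.57 ± 0.15 and Wnt5b by -2.07 ± 0.38. Sox10 rose by 3.98 ± 0.32 from 6.88 ± 1.40 CPM, Meox1 by 1.73 ± 0.18, Stra6 by 1.08 ± 0.18, Krt18 by 0.82 ± 0.12 and Car11, a carbonic anhydrase family gene, by 2.28 ± 0.41. The endoderm list passed upward with 5 of 21 higher and 1 lower (7 and 1 adjusted over the list alone; camera adjusted p = 1.8e-07, and adjusted p = 0.113 with an estimated correlation). The retinoic acid list passed upward with 4 of 9 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.0028, and adjusted p = 0.196 with an estimated correlation). Fry passed 0 of 19 lists upward, so neither the endoderm nor the retinoic acid list passed with it. It passed 5 lists downward, of which 4 also passed with camera. Hox groups 1 to 4 passed downward with 1 of 10 higher and 1 lower (1 and 4 adjusted over the list alone; camera adjusted p = 0.0129, and adjusted p = 0.113 with an estimated correlation). Wnt ligands, with 2 of 9 higher and 3 lower (2 and 4 adjusted over the list alone), and Fgf genes, with 1 of 12 higher and 1 lower (1 and 4), also passed downward (camera adjusted p = 0.0422, and adjusted p = 0.144 with an estimated correlation, for each). EdgeR called 121 genes, 73 higher and 48 lower in Triple. DESeq2 called 55 and the blue libraries alone 38, and the count was 78 without Triple replicate green-1 and 70 without Triple replicate blue-1.

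**Figure D2:**
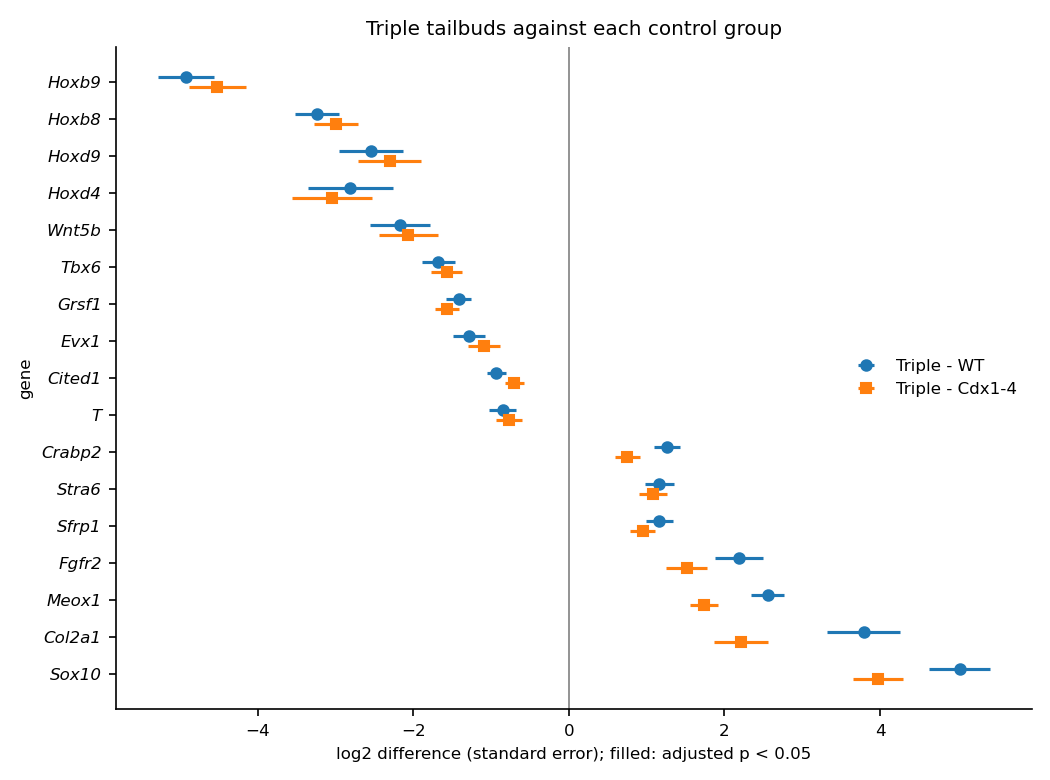
Log2 differences of selected named genes between Triple and WT tailbuds (circles) and between Triple and Cdx1-4 tailbuds (squares), with standard errors (bars) and n = 3 per group. Hoxb9 is lowest at -4.92 and Sox10 highest at 5.03 against WT, and both comparisons share the Triple libraries.

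Between 0h and 24h with Chiron and Fgf8, WT EpiSCs switched from epiblast to streak and presomitic gene expression. The labels list IWP2 at 0h and not at 24h, and no group was kept untreated for 24h. The effects of adding Chiron and Fgf8, of leaving out IWP2 and of time in culture therefore cannot be told apart, in WT or in Null cells. T rose from 52.7 ± 1.91 to 468 ± 77.9 CPM (SD, n = 2), a log2 difference of 3.16 ± 0.15 (edgeR adjusted p = 9.8e-18), Mixl1, a homeobox gene of the streak, by 4.51 ± 0.19 and Tbx6 by 5.96 ± 0.33. Of 19 measured streak genes 17 rose and 1 fell (18 and 1 adjusted over the list alone; camera adjusted p = 1.3e-22), and of 17 paraxial mesoderm genes 9 rose and 1 fell (11 and 1; 1.1e-07). Both lists lost the call with an estimated correlation (adjusted p = 0.0692 with an estimated correlation for each). Utf1, a chromatin factor of pluripotent cells, fell from 98.7 ± 14.8 to 2.29 ± 1.27 CPM (log2 difference -5.55 ± 0.29). L1td1, an RNA-binding protein gene of pluripotent cells, fell by 4.04 ± 0.19, and the DNA methyltransferase gene Dnmt3b changed by -2.25 ± 0.14. In the epiblast list 11 of 19 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 1.5e-13, and adjusted p = 0.0692 with an estimated correlation). Nkd1, a feedback inhibitor of Wnt signalling, rose from 15.8 ± 1.86 to 815 ± 23.5 CPM (log2 difference 5.69 ± 0.15, edgeR adjusted p = 2.0e-24), within a Wnt feedback list of 14 higher and 3 lower among 21 (15 and 4 adjusted over the list alone; camera adjusted p = 6.5e-15, and adjusted p = 0.0692 with an estimated correlation).

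Signalling and positional genes followed the same switch in WT cells. Lefty2, a Nodal inhibitor, rose by 3.75 ± 0.37, Bmp2 by 3.18 ± 0.34 and Bmp7 by 2.37 ± 0.21, with 9 of 15 Bmp and Nodal genes higher and 1 lower (10 and 1 adjusted over the list alone; camera adjusted p = 2.0e-07, and adjusted p = 0.0692 with an estimated correlation). Hoxb1 rose from 6.59 ± 1.27 to 123 ± 23.6 CPM (log2 difference 4.22 ± 0.25) in a list of groups 1 to 4 with 5 of 8 higher, also adjusted over the list alone (camera adjusted p = 4.5e-06, and adjusted p = 0.0692 with an estimated correlation). Of Hox groups 5 to 9, 3 of 4 rose (3 adjusted over the list alone; camera adjusted p = 0.00114, and adjusted p = 0.128 with an estimated correlation), and Hoxd9 went from 3 to 115 pooled counts, a ratio of 29.7 (exact interval 9.91 to 146). Crabp1, a retinoic acid binding protein gene, rose by 3.26 ± 0.14 to 657 ± 16.8 CPM, with 6 of 14 retinoic acid genes higher and 2 lower (6 and 3 adjusted over the list alone; camera adjusted p = 8.2e-04, and adjusted p = 0.0802 with an estimated correlation). The receptor gene Fzd10 rose by 3.90 ± 0.26 and the Wnt enhancer Rspo3 by 3.45 ± 0.39, with 8 of 19 Wnt ligands and receptors higher and 4 lower (9 and 4 adjusted over the list alone; camera adjusted p = 0.0144, and adjusted p = 0.328 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, fell by 0.74 ± 0.10, and 4 of 29 cell cycle genes were lower (8 adjusted over the list alone; camera adjusted p = 4.6e-04, and adjusted p = 0.0692 with an estimated correlation). Of 3 blood genes Lmo2 and Runx1 rose, by 4.75 ± 0.28 and 1.60 ± 0.27 (2 adjusted over the list alone; camera adjusted p = 0.00114, and adjusted p = 0.0692 with an estimated correlation). Of 10 allantois genes 2 rose and 5 fell (2 and 6 adjusted over the list alone; camera Down, adjusted p = 0.0225, and adjusted p = 0.128 with an estimated correlation), Igf2 by -1.85 ± 0.13. The allantois list did not pass with fry (fry adjusted p = 0.167).

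Fgf genes went both ways in WT cells. Fgf10 went from 1 to 119 pooled counts, a ratio of 92.1 (exact interval 16.2 to 3670), while Fgf5, a ligand of the epiblast, fell by 1.94 ± 0.25 (edgeR adjusted p = 5.4e-07) and Etv1, a transcription factor downstream of Fgf, changed by -1.44 ± 0.18. Of 20 Fgf genes 5 rose and 5 fell (6 and 6 adjusted over the list alone; camera Down, adjusted p = 0.613; median -0.18, mean 0.38). The hypoxia list leaned up without passing (9 of 22 higher, 2 lower; camera adjusted p = 0.0765, and 0.0413 with the replicate block). P53 target, fibroblast, notochord, neural, cardiac, endoderm, sex-linked and immediate early genes did not pass either (camera adjusted p from 0.139 to 0.891). Median and mean differed in sign for p53 targets (-0.01 and 0.25) and endoderm genes (-0.10 and 0.32), both tested upward. EdgeR called 1632 genes, 795 higher and 837 lower, so that 48.7% were higher, against 37.1% with scaling by library size alone. DESeq2 called 784, and the count was 1068 without WT 0h replicate 1 and 1034 without WT 24h replicate 1.

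Null EpiSCs also moved from epiblast to streak and presomitic gene expression. T rose from 13 ± 3.06 to 560 ± 80.3 CPM (SD, n = 2), a log2 difference of 5.38 ± 0.19 (edgeR adjusted p = 1.2e-20), Mixl1 by 6.39 ± 0.23, Tbx6 by 5.05 ± 0.29 and Gsc, a homeobox gene of the anterior streak, by 4.95 ± 0.28. Of 19 streak genes 17 rose (18 adjusted over the list alone; camera adjusted p = 1.8e-27), and 10 of 17 paraxial mesoderm genes (10; 8.6e-10). Both lists lost the call with an estimated correlation (adjusted p = 0.0704 with an estimated correlation for each). Sp5, a direct Wnt target, rose by 6.24 ± 0.34 to 453 ± 47.6 CPM and Nkd1 by 4.73 ± 0.18, with 15 of 21 Wnt feedback genes higher and 2 lower, also adjusted over the list alone (camera adjusted p = 5.9e-13, and adjusted p = 0.0704 with an estimated correlation). Utf1 fell by 5.62 ± 0.23 and Pou3f1, a POU factor of the epiblast, changed by -4.08 ± 0.19, with 13 of 19 epiblast genes lower and 1 higher, also adjusted over the list alone (camera adjusted p = 4.4e-14, and adjusted p = 0.0704 with an estimated correlation). The Bmp and Nodal list rose with 11 of 15 members and 1 lower, also adjusted over the list alone (camera adjusted p = 3.1e-09, and adjusted p = 0.0704 with an estimated correlation), Lefty2 by 3.71 ± 0.25. Hox groups 1 to 4 rose with 5 of 8 (6 adjusted over the list alone; camera adjusted p = 1.7e-04, and adjusted p = 0.118 with an estimated correlation), Hoxb1 by 4.94 ± 0.28. Retinoic acid genes passed upward with 6 of 14 higher and 2 lower (8 and 2 adjusted over the list alone; camera adjusted p = 0.00262, and adjusted p = 0.118 with an estimated correlation), and Crabp1 rose by 3.35 ± 0.16. Wnt ligands and receptors passed upward with 9 of 19 higher and 4 lower (10 and 5 adjusted over the list alone; camera adjusted p = 0.0151, and adjusted p = 0.363 with an estimated correlation), and Wnt6 rose by 4.70 ± 0.35. Cell cycle genes passed downward with 4 of 29 lower (3 adjusted over the list alone; camera adjusted p = 0.00262, and adjusted p = 0.118 with an estimated correlation), Mki67 by -0.69 ± 0.13. Hypoxia and glycolysis genes passed downward with 7 of 22 lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.0169, and adjusted p = 0.363 with an estimated correlation), the glucose transporter gene Slc2a3 by -0.74 ± 0.14. The hypoxia list did not pass with fry (fry adjusted p = 0.0721).

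Posterior Hox genes stayed scarce in Null cells at 24h. Hoxd9 held 0 counts at 0h and 13 at 24h, at least 3.16-fold higher (edgeR adjusted p = 0.00908), a call lost without Null 0h replicate 1 (0.0999) or Null 24h replicate 1 (0.214, the highest over its alternatives). Hoxb9 held 1 and 8 counts, a ratio of 5.83 (exact interval 0.781 to 259). Hox groups 5 to 9 did not pass (2 of 4 higher, 2 adjusted over the list alone; camera adjusted p = 0.164). Fgf8, an Fgf ligand of the streak, rose by 2.25 ± 0.27, but Fgf genes as a list did not pass (6 of 20 higher, 7 lower; 8 and 7 adjusted over the list alone; camera adjusted p = 0.612). EdgeR called 1807 genes, 891 higher and 916 lower, so that 49.3% were higher, against 39.2% with scaling by library size alone. Of the genes called in WT and in Null, which share no library, 499 were higher and 508 lower in both, where 73 and 79 would fall together by chance. Genes with more counts are easier to call in both, and the numbers by chance leave this out. Bnip3 and Pdk1 rose in WT and fell in Null, and Peg10 fell in WT and rose in Null. DESeq2 called 953, and the count was 1121 both without Null 0h replicate 1 and without Null 24h replicate 1.

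**Figure D3:**
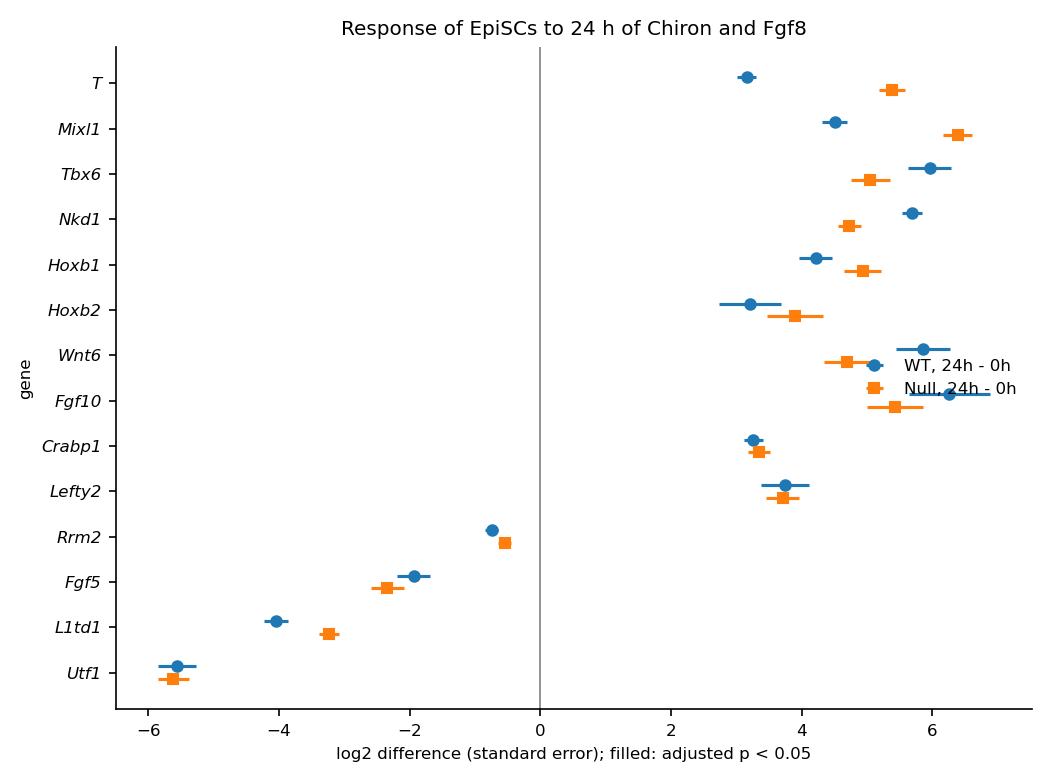
Log2 differences between 24h and 0h of selected named genes in WT (circles) and Null (squares) EpiSCs, with standard errors (bars) and n = 2 per group. T moves by 3.16 in WT and 5.38 in Null, and Utf1 by -5.55 and -5.62.

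Before the treatment, Null EpiSCs held more epiblast and less streak RNA than WT. Tdgf1, which encodes the Nodal co-receptor Cripto, stood at 701 ± 78 CPM in Null and 28.6 ± 3.43 in WT (SD, n = 2; log2 difference 4.61 ± 0.14, edgeR adjusted p = 1.9e-22), Pou3f1 was higher by 1.90 ± 0.15 and Utf1 by 1.37 ± 0.14. Of 19 epiblast genes 11 were higher (16 higher and 1 lower adjusted over the list alone; camera adjusted p = 6.4e-16, and adjusted p = 0.0858 with an estimated correlation). T was lower, with a difference of -1.98 ± 0.25 (edgeR adjusted p = 1.6e-06), at 13 ± 3.06 against 52.7 ± 1.91 CPM, and Cyp26a1, which breaks down retinoic acid, held 1 count in Null and 32 in WT, a ratio of 24.7 (exact interval 4.13 to 1006). Of 19 streak genes 4 were lower (6 adjusted over the list alone; camera adjusted p = 3.6e-08), and of 21 Wnt feedback genes 5 were lower and 1 higher (6 and 1; 1.2e-05). Both lists lost the call with an estimated correlation (adjusted p = 0.185 with an estimated correlation for each). Neural genes leaned down with 4 of 15 (6 adjusted over the list alone; camera adjusted p = 5.7e-04), the progenitor factor Olig2 by -0.76 ± 0.15, and notochord genes with 4 of 6 lower and 1 higher, also adjusted over the list alone (0.00154). For each the adjusted p = 0.159 with an estimated correlation. Hypoxia and glycolysis genes were higher with 8 of 22 up and 2 down (11 and 2 adjusted over the list alone; camera adjusted p = 4.6e-06, and adjusted p = 0.185 with an estimated correlation), Ldha by 0.77 ± 0.10 and Slc2a3 by 0.96 ± 0.14. Cell cycle genes were higher with 3 of 29 (7 adjusted over the list alone; camera adjusted p = 0.00621, and adjusted p = 0.185 with an estimated correlation). So were p53 targets with 2 of 16 (2 adjusted over the list alone; camera adjusted p = 0.0423, and adjusted p = 0.323 with an estimated correlation and 0.0591 with the replicate block). Pmaip1, which encodes the apoptosis factor Noxa, held 75 counts in Null and 2 in WT, a ratio of 48.6 (exact interval 13 to 408), and Sfn, a 14-3-3 protein gene, 92 and 1, a ratio of 119 (20.9 to 4757).

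The difference at 0h covered 647 genes, 322 higher and 325 lower in Null, so that 49.8% were higher, against 38% with scaling by library size alone and 62.8% among the 250 genes that DESeq2 called. The count was 329 without Null replicate 1, 361 without Null replicate 2, 344 without WT replicate 1 and 326 without WT replicate 2. Fgf4, an epiblast ligand, was higher by 3.21 ± 0.56 and Pcdh8, a protocadherin gene of paraxial mesoderm, by 2.09 ± 0.36 (edgeR adjusted p = 2.7e-04 and 2.0e-04). Sox17, an endoderm factor, differed by -2.07 ± 0.39. The imprinted gene Peg10 stood at 12.5 ± 1.54 CPM in Null and 53 ± 2.32 in WT, and Cap1, a regulator of actin, differed by -2.20 ± 0.25 (edgeR adjusted p = 5.5e-07 and 1.8e-07).

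After 24h, Null cells held more epiblast RNA and less posterior Hox RNA than WT. Tdgf1 reached 2049 ± 54 CPM in Null and 59.7 ± 6.67 in WT (SD, n = 2; log2 difference 5.12 ± 0.13, edgeR adjusted p = 1.7e-25), and Pou5f1, which encodes Oct4, was higher by 0.99 ± 0.15 and L1td1 by 1.69 ± 0.24. Of 19 epiblast genes 6 were higher and 1 lower (10 and 1 adjusted over the list alone; camera adjusted p = 3.4e-08, and adjusted p = 0.194 with an estimated correlation). Hoxd9 stood at 3.39 ± 2.91 CPM in Null and 27.1 ± 5.86 in WT (log2 difference -2.83 ± 0.42, edgeR adjusted p = 1.9e-05). All 4 tested genes of Hox groups 5 to 9 were lower (4 adjusted over the list alone; camera adjusted p = 8.3e-05, and adjusted p = 0.194 with an estimated correlation). Hoxb9, at 2.07 ± 1.98 against 15.8 ± 6.16 CPM, differed by -2.84 ± 0.53 (edgeR adjusted p = 4.4e-04), and lost its call without WT 24h replicate 1 (0.0813, the highest over its alternatives). Nkd1 was lower in Null, at 308 ± 1.19 against 815 ± 23.5 CPM, a difference of -1.40 ± 0.11 (edgeR adjusted p = 1.1e-11), although the Wnt feedback list did not pass (2 of 21 higher, 3 lower; 2 and 7 adjusted over the list alone; camera Down, adjusted p = 0.207).

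Some streak and mesoderm genes stood higher in Null cells at 24h. Eomes, a T-box gene of the streak, was higher by 1.01 ± 0.16, Mixl1 by 0.68 ± 0.12 and Pcdh8 by 2.04 ± 0.37, while T, at 560 ± 80.3 and 468 ± 77.9 CPM, differed by 0.25 ± 0.12 (edgeR adjusted p = 0.215). Of 19 streak genes 5 were higher (6 adjusted over the list alone; camera adjusted p = 0.0104), of 17 paraxial mesoderm genes 5 (7; 0.0104), and of 13 endoderm genes 5 with 1 lower (6 and 2; 0.0104), Krt8 by 2.68 ± 0.33. These 3 lists lost the call with an estimated correlation (adjusted p = 0.556, 0.443 and 0.465 with an estimated correlation). They also lost it with fry (fry adjusted p = 0.303, 0.124 and 0.303). Cell cycle genes were higher with 3 of 29 (3 adjusted over the list alone; camera adjusted p = 0.00509), p53 targets with 2 of 16 (2; 0.0104), and neural genes lower with 4 of 15 (4; 0.00364), Olig2 by -1.19 ± 0.22. These 3 did not pass with an estimated correlation (adjusted p = 0.204, 0.375 and 0.194 with an estimated correlation). With fry they did (fry adjusted p = 0.0216, 0.00667 and 0.00923). Cdkn1c, a cell cycle inhibitor gene, was higher by 3.53 ± 0.24. Wnt ligands and receptors (2 of 19 higher adjusted over the list alone; camera adjusted p = 0.323), Fgf genes (1 of 20 higher; 0.693) and Hox groups 1 to 4 (camera Down with 1 of 8 higher, and 2 higher and 2 lower adjusted over the list alone; 0.693) did not pass. EdgeR called 781 genes, 359 higher and 422 lower in Null, so that 46% were higher, against 35.3% with scaling by library size alone. DESeq2 called 264, thinning every library to the lowest total left 480, and the count was 364 without Null 24h replicate 1, 357 without Null 24h replicate 2 and 370 without WT 24h replicate 1. Of the genes called at 0h and at 24h, in different libraries, 125 were higher and 122 lower at both times, where 11.9 and 14.1 would by chance. Null cells were compared with WT cells at both times, so a lasting difference between them recurs. The numbers by chance leave this out, and also that genes with more counts are easier to call.

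**Figure D4:**
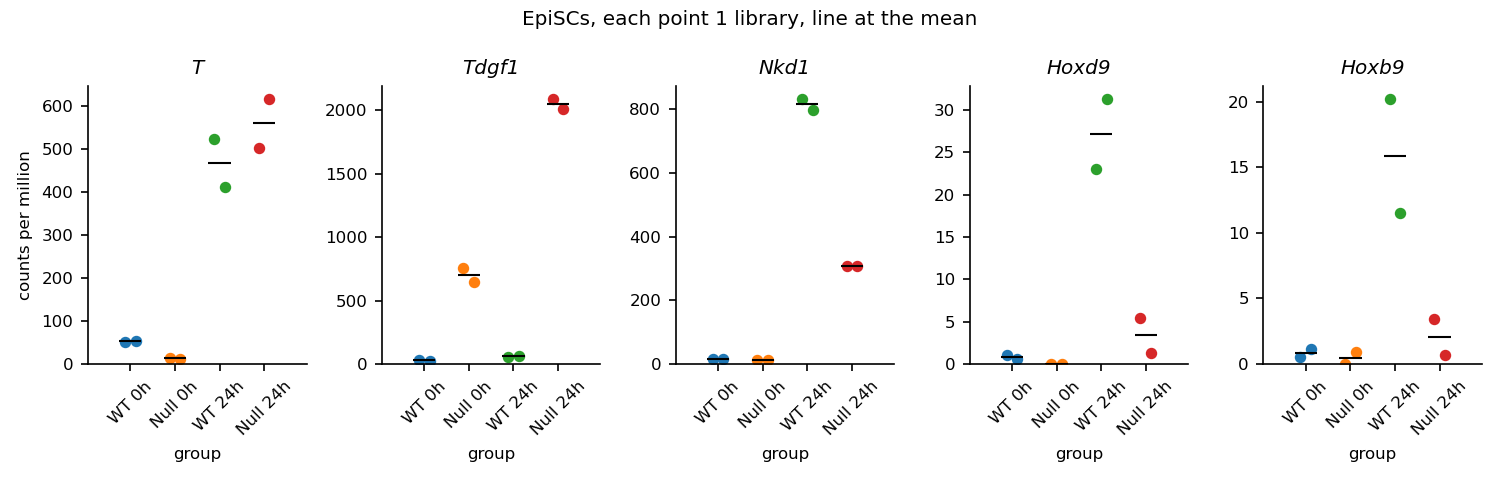
CPM of T, Tdgf1, Nkd1, Hoxd9 and Hoxb9 in each EpiSC library (points, n = 2 per group) with group means (lines). Tdgf1 is higher in Null libraries at both times, while Nkd1, Hoxd9 and Hoxb9 are lower in Null than in WT libraries at 24h.

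The response itself differed between Null and WT cells in 55 genes, 33 with a higher and 22 with a lower response in Null. T rose more in Null by 2.22 ± 0.28 (edgeR adjusted p = 4.4e-05) and Cyp26a1 by 5.07 ± 0.81 (0.00109), from 1 pooled count at 0h. Upp1, a uridine phosphorylase gene, rose more by 2.44 ± 0.43, from 5.10 to 217 CPM in Null and 14.6 to 109 in WT. Of 19 streak genes 5 responded more in Null (7 adjusted over the list alone; camera adjusted p = 2.6e-15), and of 22 hypoxia genes 2 responded less (6 less and 1 more adjusted over the list alone; 3.4e-07). Both lists lost the call with an estimated correlation (adjusted p = 0.2 with an estimated correlation for each) and with fry (adjusted p = 0.117 and 0.227). Igf2, an imprinted growth factor, fell in both lines and less in Null (difference 1.25 ± 0.19, edgeR adjusted p = 8.2e-04). The notochord list passed upward with 1 of 6 genes called (2 adjusted over the list alone; camera adjusted p = 1.6e-06, and adjusted p = 0.127 with an estimated correlation). Wnt feedback genes passed upward with 3 of 21 higher (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0211, and adjusted p = 0.425 with an estimated correlation). The Bmp and Nodal list passed upward with 0 of 15 called and the paraxial mesoderm list with 1 of 17 (2 and 4 adjusted over the list alone; camera adjusted p = 0.01 and 0.0111, and adjusted p = 0.377 with an estimated correlation for each). Of 10 allantois genes 1 was called (2 higher and 1 lower adjusted over the list alone; camera Up, adjusted p = 0.0344, and adjusted p = 0.343 with an estimated correlation). Hox groups 5 to 9 passed downward with 0 of 4 called, also adjusted over the list alone (camera adjusted p = 0.0322, and adjusted p = 0.377 with an estimated correlation), although the median was 0.38 and the mean 0.35. Of 21 lists fry passed 1, the notochord list upward (fry adjusted p = 0.00642). The Wnt feedback, Bmp and Nodal, and paraxial mesoderm lists did not pass with it (fry adjusted p = 0.323 each). Hox groups 5 to 9 (0.323) and allantois genes (0.495) did not either. DESeq2 called 24 genes and thinning left 33, whereas leaving out the filter gave 93 and the replicate block 123. The count was 82 without WT 24h replicate 2, 18 without Null 0h replicate 1, 19 without Null 24h replicate 1, 27 without WT 0h replicate 1 and 30 without WT 0h replicate 2.

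Null EpiSCs at 24h and Triple tailbuds, each against its own WT libraries, shared part of their changes. Of 5909 genes tested in both, 10 were lower in both, where 2.89 would by chance (Fisher's exact test, two-sided, p = 5.3e-04), among them Hoxb8, Hoxd9 and Tecr. A further 15 were higher in both, where 4.05 would by chance (Fisher's exact p = 9.3e-06), among them Krt8, Pcdh8 and Aldh1a2. Genes also overlapped in opposite directions, 6 higher in Null and lower in Triple (expected 2.96, Fisher's exact p = 0.0741) and 10 lower in Null and higher in Triple (expected 3.96, p = 0.00586). With DESeq2 calls 6 genes overlapped in the same direction, 2 higher, no longer beyond chance (Fisher's exact p = 0.156), and 4 lower (p = 0.0011). Without Triple replicate blue-2 the shared higher genes numbered 7 (Fisher's exact p = 0.04), and without Null 24h replicate 2 or the tailbud WT replicate green-1 there were 9 (p = 1.1e-04 and 0.00127). Without WT 24h replicate 1 the shared lower genes numbered 6 (Fisher's exact p = 0.00206). Genes with more counts are easier to call in both cells and tailbuds, and the numbers by chance leave this out. These lists of shared genes were read after the values were seen.

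Cdx2 and T binding was mapped in EpiSCs at 24h to ask where the factors meet. Cdx2 replicates held 1210 and 2545 regions, with 88.9% of the first overlapping the second and 42.4% the reverse, and T replicates 1246 and 1079, with 61.6% and 71.1%. These gave 1075 Cdx2 sites and 767 T sites, of which 42 coincided, 3.91% of Cdx2 sites (95% Wilson interval 2.90 to 5.24) and 5.48% of T sites (4.08 to 7.32), against shuffled means of 0.013% and 0.0287%. Over 55973 open regions of CdxKO EpiSCs, 25 held both factors where 2.26 would by chance (odds ratio 12.7, interval 7.95 to 19.3, Fisher's exact p = 1.2e-18). Over 13549 CBP-P300 regions, marked by co-activators, the odds ratio was 3.68 (0.0893 to 22.6, Fisher's exact p = 0.246), with 1 region that held both. The 5 widest co-bound sites, chosen after the data were seen because the lists hold no scores, lay in mm9 at 1:18181403-18182122, 6:122605082-122605775, 17:27790054-27790662, 16:96091159-96091761 and 10:29575584-29576134. Of these, the chromosome 16 site was open at 48h and carried H3K27ac and CBP-P300 in EpiSCs and H3K27ac in both E9.5 tissues. The chromosome 10 site was open at 48h and carried H3K27ac in EpiSCs and tailbud. The chromosome 1 and 17 sites were open at 48h without H3K27ac or CBP-P300, and the chromosome 6 site had none of these features.

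Open chromatin of CdxKO cells was used to ask which bound sites are accessible without Cdx, from 1 library at 0h and 1 at 48h. With 1 library per time, the difference between the times is given as values without a test. Of Cdx2 sites 27.4% (95% Wilson interval 24.9 to 30.2) were open at 0h and 35.3% (32.5 to 38.3) at 48h, a difference of 7.91 percentage points (117 sites open at 48h alone and 32 at 0h alone). Of T sites 15.1% (12.8 to 17.8) were open at 0h and 39.2% (35.9 to 42.7) at 48h, a difference of 24.1 points (193 against 8 sites). Of 54680 open regions without either factor, 11473 were open at 48h alone and 9697 at 0h alone, and against this background the odds of being open at 48h alone rather than at 0h alone were 3.09-fold for Cdx2 sites and 20.4-fold for T sites. Shuffled sites were open in 1.75% to 1.92%. Of the regions open at 48h 74.5% overlapped a region open at 0h, and 78.2% the reverse. H3K27ac in EpiSCs covered 24% of Cdx2 sites (21.5 to 26.6) and 14.6% of T sites (12.3 to 17.3), and CBP-P300 11.3% (9.5 to 13.3) and 3.78% (2.65 to 5.38). With regions of either replicate instead of both, Cdx2 sites were open at 48h in 30.8%, T sites in 29.3%, and Cdx2 sites carried H3K27ac in 18.9% and CBP-P300 in 7.14%.

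At E9.5, sites bound by Cdx2 in EpiSCs carried H3K27ac more often in the tailbud than in anterior tissue. The mark covered 63.6% of Cdx2 sites in tailbud (95% Wilson interval 60.7 to 66.4) and 34.7% in anterior tissue (31.9 to 37.6), a difference of 28.9 points (335 sites in tailbud alone and 24 in anterior alone, exact McNemar p = 2.8e-71). For T sites it was 30% (26.9 to 33.3) and 12% (9.88 to 14.5), a difference of 18 points (152 against 14, exact McNemar p = 1.9e-30). Open regions without either factor split 3703 against 3920, a difference of -0.397 points, and shuffled sites were covered in 3.46% to 4.41%. These values come from replicate 2, since the labels say that the antibody batch of replicate 1 also binds H3K9ac; with replicate 1 the differences were 22.8 and 6.52 points. The p-values over sites cover no variation between libraries of a tissue. The tailbud list was the longer, with 76071 regions against 61674, and 56.1% of tailbud regions overlapped an anterior one. Cdx2 sites that also held T were open at 48h more often than the other Cdx2 sites, 59.5% against 34.4%, and carried H3K27ac less often in anterior tissue, 11.9% against 35.6%, and in tailbud, 40.5% against 64.6% (Fisher's exact, Benjamini-Hochberg adjusted p = 0.00869, 0.00869 and 0.011 over 12 tests). Among T sites, those with Cdx2 were open at 48h more often than the others, 59.5% against 38.1% (adjusted p = 0.0257, Fisher's exact). Their H3K27ac leaned the other way than among Cdx2 sites, without passing. It was 14.3% against 11.9% in anterior tissue and 40.5% against 29.4% in tailbud (Fisher's exact, adjusted p = 0.795 and 0.329).

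**Figure D5:**
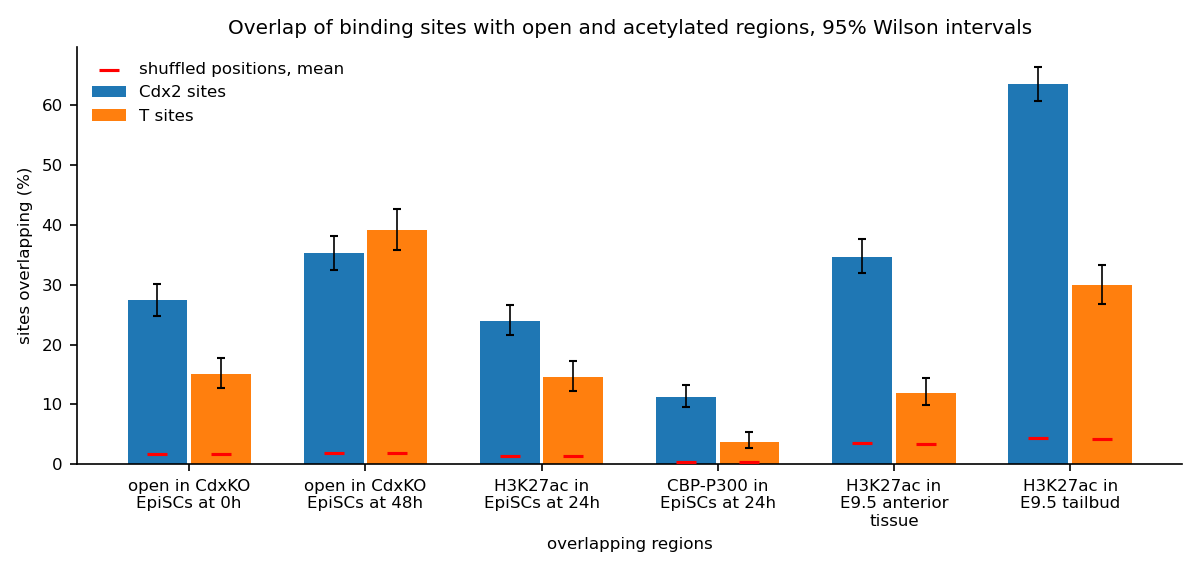
Percent of Cdx2 and T sites that overlap open regions of CdxKO EpiSCs, H3K27ac or CBP-P300 in EpiSCs at 24h, and H3K27ac in E9.5 tissues (bars, from 0), with 95% Wilson intervals and the mean of 100 shuffles (red marks). Cdx2 sites reach 63.6% in tailbud H3K27ac and T sites 39.2% in regions open at 48h.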

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

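The comparisons of starting levels in Null cells, over the streak genes and for T alone, were chosen after the result was seen. So was the thinning to equal library totals with the size of the differences after it. The 24h response differed between Null and WT EpiSCs in 55 genes by the interaction test of edgeR, and this difference between the cell lines is what drew attention to them. Among the named genes, the response in Null minus that in WT was 2.22 for T, 1.88 for Mixl1, 5.07 for Cyp26a1, 1.34 for Dll3, 2.30 for Gata6, 1.25 for Igf2, 2.79 for Asb4, 3.86 for Klhl6 and 2.44 for Upp1 on the log2 scale. It was -1.52 for Bnip3, -2.22 for Pdk1, -1.76 for Pim1, -3.53 for Myb, -1.94 for Cep250 and -1.60 for Rnf165. The calls of T, Cyp26a1, Upp1 and Igf2 held under every alternative run, and the others were lost under at least 1.

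The fixed streak genes were lower in Null cells at 0h, with a median of -1.21, and stood at a median of 0.26 at 24h (camera adjusted p = 0.0104, and adjusted p = 0.556 with an estimated correlation), so a lower start stays open for them. For T alone the difference went from -1.98 at 0h to 0.25 at 24h (edgeR adjusted p = 0.215). These values are the terms of the difference in response, so they describe a lower start and cannot test it as the cause. It stays open for T too. After thinning to the lowest total, the median difference in response over the 33 genes that rose more in Null was 1.48 against 1.47 before. The lowest ratio for any of them was 0.832. Thinning keeps the expected ratios between groups, so these sizes cannot decide whether unequal library totals play a part, which stays open. Calls stayed for 20 of the 33, 60.6% (95% Wilson interval 43.7 to 75.3), and for 30 of all 55, so the bound set before the test, an interval above 50%, was missed, while the median standard error grew from 0.29 to 0.35. The genotype of the Null line stays among the open explanations, as untested.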

How the results depend on the processing

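Thinning, the colour block and the blue libraries alone were chosen after the data were seen. No called named gene changed sign under an alternative (0 of 3507 values), while 12 of 164 lists, none past the threshold, had another direction by fry than by camera. Of 330 named gene values 254 were called, and 169 of these stayed called under every alternative. Calls were lost for 37 of 229 with DESeq2, 25 of 78 with the blue libraries alone, 22 of 246 after thinning and 182 of 1234 when a library was left out, against 1 to 3 of 254 under other scalings.

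Genes called by DESeq2 numbered 784 and 953 for 24h against 0h in WT and Null, 250 and 264 for Null against WT at 0h and 24h, 24 for the interaction, and 91, 4 and 55 for Triple against WT, Cdx1-4 against WT and Triple against Cdx1-4. Thinning left 480 at 24h and 33 in the interaction, which fewer counts explain, and the blue libraries alone gave 74 and 38 for Triple against WT and Cdx1-4, with 2 libraries per group instead of 3. The replicate block gave 123 genes in the interaction and leaving out the filter 93. The cause was not tested for DESeq2, the block or the filter. Over the fits without 1 library, the counts ran from 1034 to 1584 (WT), 1121 to 1424 (Null), 326 to 361 (0h), 357 to 796 (24h), 18 to 82 (interaction), 125 to 154 (Triple against WT), 6 to 11 (Cdx1-4 against WT) and 70 to 110 (Triple against Cdx1-4). In the EpiSC fits the lone library of a group is assumed to vary like the other groups. The embryo columns carry no replicate number of the titles, so their libraries were not paired by it, and the column colour as a block gave 181, 7 and 124 genes.

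Of 164 list tests 59 passed by camera, 4 with an estimated correlation and 53 with fry, of which 42 were among the 59. The cause was not tested. The overlap of Null cells at 24h with Triple embryos fell from 25 genes to 6 with DESeq2 calls, which are fewer. With either replicate, open Cdx2 and T sites at 48h came to 30.8% and 29.3%, and Cdx2 sites with H3K27ac and CBP-P300 to 18.9% and 7.14%; regions of 1 replicate alone enter by construction. Under 50% reciprocal overlap, ATAC regions shared between times came to 64.9% and tailbud H3K27ac regions shared with anterior tissue to 41.8%, by the stricter rule, and to 56.5% with the other antibody batch. Over CBP-P300 regions the odds ratio of binding was 3.68, with 1 region that held both.

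Not run were the alternatives with higher-scoring peaks alone, since the lists hold no scores, distances of sites to genes, since no mm9 annotation was used, and a pseudocount, since the tables hold counts. Depth limits the Cdx1 and Cdx4 counts in EpiSCs, which were too low to test. Of simulated genes with a log2 difference of 1, 29.3% were called in the interaction, and depth was not separated there from the number of libraries.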

Other observations

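The thinning to equal library totals reported here was chosen after the results were seen, as were the genes of the next 2 paragraphs.

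Genes that changed in WT EpiSCs over 24h also changed in Triple tailbuds more often than if the calls were independent, in every combination of directions. Genes with more counts are easier to call in both cells and tailbuds, and the number by chance leaves this out. Of 5909 genes tested in both, 27 rose in EpiSCs and fell in Triple where 6.18 would by chance (Fisher's exact p = 6.4e-12), among them T and Tbx6 of the streak and presomitic mesoderm, Evx1, Grsf1, Cited1, Hoxb8, Hoxb9 and Hoxd9. In reverse, 22 genes fell in EpiSCs and rose in Triple tailbuds where 7.02 would by chance (Fisher's exact p = 9.0e-07), among them Meox1, Sfrp1, Fzd2 and Igf2. Another 22 rose in both (expected 8.46, Fisher's exact p = 2.0e-05), among them Aldh1a2 and Stra6 of the retinoic acid pathway, and 11 fell in both (expected 5.13, Fisher's exact p = 0.0165), among them Rrm2.

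Eif2s3y, a translation factor gene of the Y chromosome, was higher in Null than in WT EpiSCs by 2.88 ± 0.31 at 24h (edgeR adjusted p = 3.6e-08). Ddx3y, on the same chromosome, held 155 and 155 CPM in the Null libraries at 0h and 94.2 and 90 in WT. Kdm5d, also on it, differed by -0.66 ± 0.32 at 24h (edgeR adjusted p = 0.215), and Uty by 0.53 ± 0.60 (0.676). The embryonic globin genes Hbb-bh1 and Hba-x stood at 87.1 and 177 CPM in Cdx1-4 replicate blue-1, and at no more than 20.8 and 33 CPM in the other embryo libraries.

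The genes that differed between Null and WT EpiSCs at 0h were tested for linkage to the Cdx genes, since DNA of another strain beside a targeted gene would change its neighbours. The labels do not name the loci targeted in Null cells, apart from a mention of cells null for Wnt3, and other loci were not tested. Of the called genes with a position 26 of 645 lay within 20 Mb of a Cdx gene, 4.03% (95% Wilson interval 2.77 to 5.84), against 3.63% of uncalled genes (odds ratio 1.11, Fisher's exact p = 0.587). No excess of called genes beside the Cdx genes was seen. Few genes lie within this window, so the test could hardly have shown such DNA as the source of most calls. After thinning to equal library totals 491 of 647 calls stayed, 75.9% (72.5 to 79.0), so most do not need unequal totals in the edgeR test. Thinning keeps the expected ratios between groups, so it cannot decide whether unequal totals shifted those ratios, which stays open. No biological explanation was tested.

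The lower Hox genes of groups 5 to 9 and higher Meox1 and Sox10 in Triple tailbuds could come from a larger share of other tissue in the dissected piece. A larger share of all other tissues would raise all their genes, and a share of particular tissues only theirs. Of the 4 testable lists of other tissues 0 passed downward. Endoderm genes passed upward (5 of 21 higher and 1 lower, camera adjusted p = 9.8e-05), but not with an estimated correlation (adjusted p = 0.18) or fry (0.108). The median was 0.30 for endoderm, 0.39 for allantois, 0.66 for notochord and -0.06 for neural genes. The decidua gene Prl8a2 held 35 counts in Triple and 1 in WT. The values do not exclude a changed share of 1 tissue, so this stays open. After thinning to equal library totals 132 of 174 calls stayed, 75.9% (95% Wilson interval 69.0 to 81.6). Most calls thus do not need unequal totals in the edgeR test. Since thinning keeps the expected ratios between groups, it cannot decide whether unequal totals shifted those ratios, which stays open. The genotype behind the group name Triple, which the labels do not spell out, stays among the open explanations.

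The 6 embryo libraries of each comparison were split in all 10 ways into groups of 3. Of these, 1 gave as many called genes as the real groups in each comparison, the real split itself. The real splits gave 174 genes for Triple against WT, 8 for Cdx1-4 against WT and 121 for Triple against Cdx1-4, and the highest other splits 0, 1 and 4. With 10 splits there are too few for a share under 0.05.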
